A study of Danio rerio with 7 samples.

How the data were processed

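RNA was measured in 7 libraries of cells sorted from brains of 3-month-old gfap:GFP transgenic zebrafish, a line in which green fluorescent protein is made under control of the gene for glial fibrillary acidic protein and marks ependymoglia, the radial glia-like cells that line the brain ventricles. Per the labels' protocols, cells were separated by GFP brightness, RNA was isolated with a low-input kit, cDNA was made with SMART-Seq v4, and libraries were sequenced as paired reads of 100 bases on an Illumina HiSeq. The animals were untreated. The 7 libraries were grouped by title into 4 GFP high (replicates 1 to 4) and 3 GFP low (replicates 3 to 5). The labels do not say whether replicates came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

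The deposited file of each library lists 51033 Ensembl zebrafish transcripts with their length, effective length, estimated count and TPM. The estimated counts are the authors' values, not normalized and for many transcripts not whole; kallisto, sleuth and the build danRer10 are named in the submitters' processing notes, and the versions, the transcript release and the options are not given in the sources used here. kallisto assigns read pairs to transcripts by compatibility and shares out pairs that match several, so the estimates of near-identical transcripts and of isoforms of one gene are uncertain and no strand or bootstrap information accompanies them. The TPM values are also the authors' own, deposited beside the counts, and sum to the same total in each library. Length and effective length in bases are other deposited columns; their difference follows the mean fragment length. The files name transcripts only by identifier. The reference tables used here pair symbols with gene identifiers and RefSeq accessions, and 0 of the transcript identifiers matched them. Transcripts as deposited therefore took the place of genes, as the plan fixed before the data were examined allowed. Endogenous gfap, the 22 gene lists fixed beforehand (aryl hydrocarbon receptor pathway, brain cell types and cell states), the mitochondrial and ribosomal protein shares and the test counted by gene were not analysed here, and no genomic coordinates are given.

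Estimated counts were rounded to whole numbers. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) with TMM scaling, filterByExpr at its defaults with the groups, a robust fit and Benjamini-Hochberg adjustment at a false discovery rate (FDR) of 0.05. The log2 fold change is GFP high minus GFP low, and its standard error is the fold change divided by the square root of F. CPM values are TMM-scaled. Measures of library composition were compared by an exact permutation test of the absolute difference of means over the 35 splits of 7 libraries into 4 and 3, whose smallest possible p is 0.0286. The naming rule fixed beforehand took the largest changes among transcripts past 5% FDR with an average log2 CPM of at least 4 and no overlap between the groups, on condition of a gene symbol. That condition could not be applied, so only the transcript with the largest change in each direction is named; the most abundant call without overlap in each direction is named too, and was chosen after its values were seen.

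Total estimated counts ran from 10629958 to 25545771 per library. The limit that a count of 0 allows, 3 counts, corresponds to 0.123 to 0.266 CPM. Intervals on counts and shares are exact 95% intervals and cover counting error only, since reads without molecular identifiers are not independent molecules. In data simulated for this comparison from the real means and library sizes, 31739 transcripts were tested and 200 were changed. Of these, 10 of 100 changed 2-fold and 61 of 100 changed 4-fold were recovered, with 8 false calls. That is more than 5% false among the calls of this 1 simulation. Far fewer transcripts changed than the 7223 called in the real data, which makes the adjustment stricter. The shares recovered therefore do not carry over to the real data. Every pair of libraries of a group differed by more than sampling noise: the mean chi-square per degree of freedom over transcripts with at least 100 summed counts was 19.7 or more, where 1 is counting noise, so no library was counted as a copy of another.

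The alternatives were DESeq2 1.42.0, median-of-ratios size factors, no filter on low counts, a filter of at least 5 CPM in 3 libraries, offsets for effective length, limma 3.58.1 on log2(TPM + 1) and log2(TPM + 0.1) for transcripts with at least 1 TPM in 3 libraries, counts thinned to the smallest library, removal of the 10 most abundant transcripts, a fit with robust=FALSE, the replicate number as a block, and leaving out each library in turn. Library size alone as the scaling, a lowess correction on transcript length, and a fit on transcripts with whole counts in every library (within 1e-06; the largest counts are deposited without decimals and pass in any case) were added after the data were seen.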

Results

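Transcriptomes were compared between bright (GFP high, 4 libraries) and dim (GFP low, 3 libraries) cells sorted from untreated adult gfap:GFP zebrafish brains. The submitters label both as ependymoglial cells, and no marker was analysed here that tests this identity. Ependymoglia line the ventricles of the fish brain and act there as neural stem and progenitor cells. The series concerns the aryl hydrocarbon receptor, a ligand-activated transcription factor, in neurogenesis after injury. These libraries address how cells with strong and weak reporter signal differ in untreated animals. Total estimated counts were 23229811, 20076316, 24699693 and 25545771 in GFP high replicates 1 to 4, and 10629958, 21796218 and 12994388 in GFP low replicates 3 to 5. Between 37147 and 38989 of the 51033 transcripts were detected with at least 1 count per library. The transcripts carry no gene names in the tables used here, so groups of transcripts are described by direction, size of change, abundance and length.

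The bright and dim cells differed in the level of many transcripts. Of 33178 transcripts tested, 7223 (21.8%) passed 5% FDR in edgeR's quasi-likelihood test, 3372 higher in GFP high and 3851 higher in GFP low. The larger changes lay more often on the GFP low side: 2839 transcripts were at least 2-fold higher in GFP low against 1885 in GFP high, and 1595 against 740 were at least 4-fold higher. Changes of at least 16-fold numbered 544 towards GFP low and 229 towards GFP high. At a mean of 1 to 10 TPM, 1761 calls were at least 2-fold higher in GFP low and 818 in GFP high. At 100 to 1000 TPM the balance of such calls turned, with 71 and 206. Fold counts by direction were not repeated with libraries left out or at one depth. In GFP high 3 counts correspond to 0.123 to 0.159 CPM, against 0.141 to 0.266 CPM in GFP low. Large folds towards GFP low could thus be reached more easily. With GFP low replicate 4 left out, the balance of all calls turned, to 3509 higher in GFP high against 3140 higher in GFP low, so which side held more calls rests on that library. The counts of at least 16-fold changes include transcripts with 0 counts in every library of the other group, for which the fitted fold is no bound; without them, 439 and 119 remained. In 7121 of the 7223 calls (98.6%), no GFP high library overlapped any GFP low library; over all tested transcripts 35.2% were without overlap, and chance gives 5.71%. With library size alone as the scaling, 35.6% of calls were higher in GFP high in place of 46.7%, and the median log2 fold change of all tested transcripts moved from 0.0051 to -0.12, so directions of small changes are relative to the TMM scaling.

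**Figure D1:**
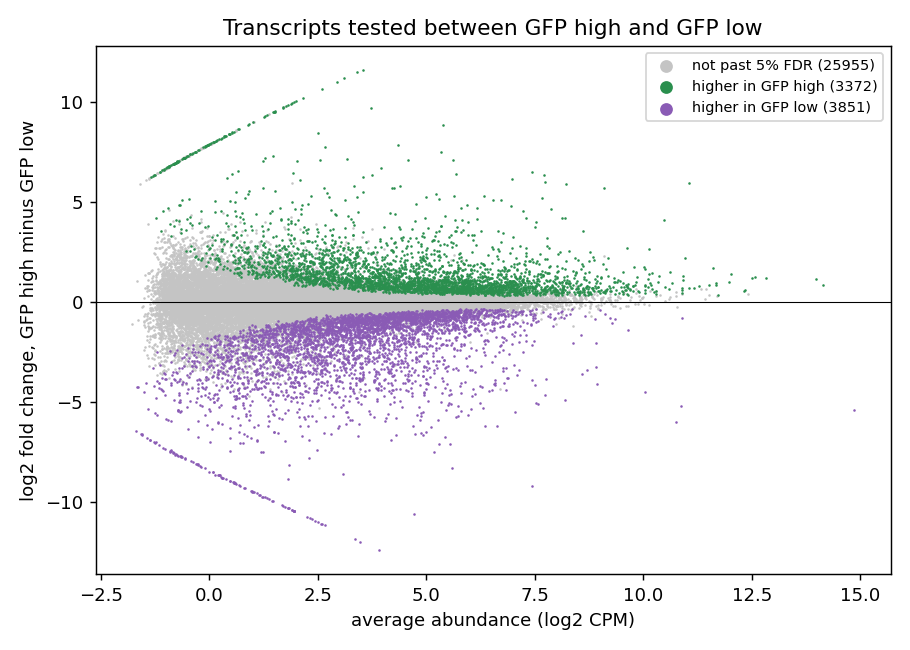
Log2 fold change (GFP high minus GFP low) against average abundance (log2 CPM) for each of the 33178 transcripts tested, with the 3372 higher in GFP high in green, the 3851 higher in GFP low in purple and the others in grey. Straight diagonal rows of points are transcripts at 0 counts in every library of 1 group, whose fitted fold depends on the prior count.

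The libraries separated by group along the first principal component, which held 49.1% of the variance of log2 CPM. All 4 GFP high libraries lay between -107 and -96.4 on it and all 3 GFP low libraries between 118 and 151. Pearson's r across transcripts, which are not independent replicates, was 0.92 to 0.93 between GFP high libraries, 0.889 to 0.892 between GFP low libraries and 0.798 to 0.831 between libraries of different groups.

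Changes among abundant transcripts were mainly towards the bright cells. Among the 1467 transcripts with a mean of at least 100 TPM, 661 were higher in GFP high, 111 were higher in GFP low and the others did not pass the test. Among the 71 transcripts over 1000 TPM, 50 were higher in GFP high (70.4%) and 4 in GFP low (5.63%). Below 10 TPM the balance lay the other way, with 1065 of 20477 transcripts higher in GFP high and 2248 higher in GFP low. The median log2 fold change of all tested transcripts was -0.089 at 1 to 10 TPM. It was 0.42 at 100 to 1000 TPM and 0.75 over 1000 TPM. Abundance classes based on the mean of the group means gave 638 and 118 calls at 100 TPM or more. Of the calls at a mean of at least 100 TPM over the 7 libraries, 85.6% were higher in GFP high. Over the alternatives this proportion ran from 77.4% with the replicate number as a block to 90.6% on transcripts with whole counts. No alternative corrected for a trend with abundance, so this range does not test whether such a trend is technical.

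**Figure D2:**
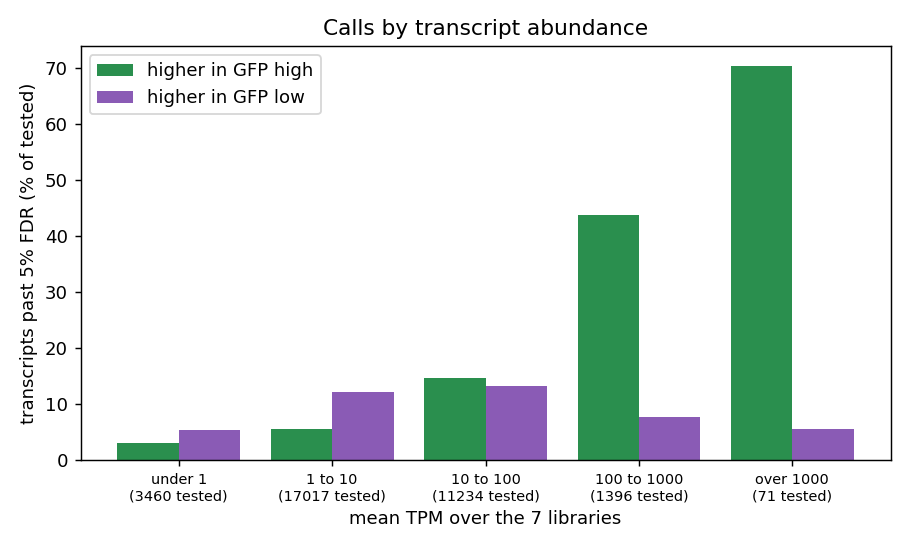
Share of tested transcripts past 5% FDR (y axis, percent) by mean TPM over the 7 libraries (x axis), with transcripts higher in GFP high in green and those higher in GFP low in purple. Calls higher in GFP high made up 5.64% of transcripts at 1 to 10 TPM and 70.4% of those over 1000 TPM, and calls higher in GFP low 12.1% and 5.63%.

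The called transcripts made up a large part of the RNA in both populations. The 3372 transcripts higher in GFP high held 43.8% ± 0.854 of estimated counts in GFP high (SD, n = 4) and 24.1% ± 0.332 in GFP low (SD, n = 3). The 3851 transcripts higher in GFP low held 5.39% ± 0.195 of estimated counts in GFP high (SD, n = 4) and 22.5% ± 2.88 in GFP low (SD, n = 3). These shares describe sets chosen on the same libraries and were not tested. Of the 22.5% in GFP low, 6.97 percentage points came from ENSDART00000171617.1 alone. In TPM this transcript weighed more. The 3851 transcripts held a mean of 28.9% of TPM in GFP low, of which it made up 15.4 percentage points, and 3.96% in GFP high. The 3372 transcripts held 47.0% of TPM in GFP high and 24.2% in GFP low. Of the 100 most abundant transcripts of each group, 71 were common to both. The GFP high list held 74 transcripts called higher in GFP high and 2 called higher in GFP low, and the GFP low list held 46 and 20.

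The most abundant transcript of the dim cells was far lower in the bright cells. ENSDART00000171617.1, of 890 bases, was at 154386 TPM ± 28583 in GFP low (SD, n = 3), and at 3526 ± 1705 in GFP high (SD, n = 4). It took 6.97% ± 1.73 of the estimated counts of the GFP low libraries (SD, n = 3) and 0.15% ± 0.0732 of those of the GFP high libraries (SD, n = 4). Its log2 fold change was -5.42 ± 0.46 (SE), a 42.9-fold higher level in GFP low, with adjusted p = 0.000227 in edgeR's quasi-likelihood test. Its estimated counts were whole in all 4 GFP high libraries, the form they take when no read pair is shared out between transcripts; the larger counts of the GFP low libraries are deposited without decimals and cannot show this. Because TPM sums to the same total in each library, this transcript by itself also lowered the TPM of all others in GFP low. It did not set the net scaling of counts. TMM factors, where a higher factor lowers CPM, were 1.06, 0.977 and 1.12 in GFP low replicates 3 to 5 and 0.944 to 0.985 in GFP high. The most abundant transcript that was higher in GFP high without overlap was ENSDART00000010477.7, of 2358 bases, at 15729 TPM ± 519 in GFP high (SD, n = 4) and 7372 ± 606 in GFP low (SD, n = 3). Its log2 fold change in CPM was 1.13 ± 0.14 (SE), with adjusted p = 0.00089 by edgeR.

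The transcripts with the largest changes under the naming rule were close to absent from the other group. ENSDART00000161321.1, of 744 bases, was at 73.0 CPM ± 13.4 in GFP high (SD, n = 4) and 0.174 ± 0.173 in GFP low (SD, n = 3), with a log2 fold change of 8.85 ± 0.50 (SE) and adjusted p = 5.35e-05 by edgeR. It rested on 6592 counts against 7, a ratio of 492 with a counting interval of 238 to 1223. Its log2 fold change was 10.06 without GFP low replicate 5 and 8.04 without GFP low replicate 4. ENSDART00000098822.4, of 3032 bases, was at 61.4 CPM ± 28.8 in GFP low (SD, n = 3), with 2807 counts there against 3 in GFP high, all in replicate 3. The ratio was 1792 with a counting interval of 613 to 8697, and the adjusted p by edgeR was 6.55e-05. Both transcripts had estimated counts that were not whole, so their values depend in part on how kallisto shared out reads.

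**Figure D3:**
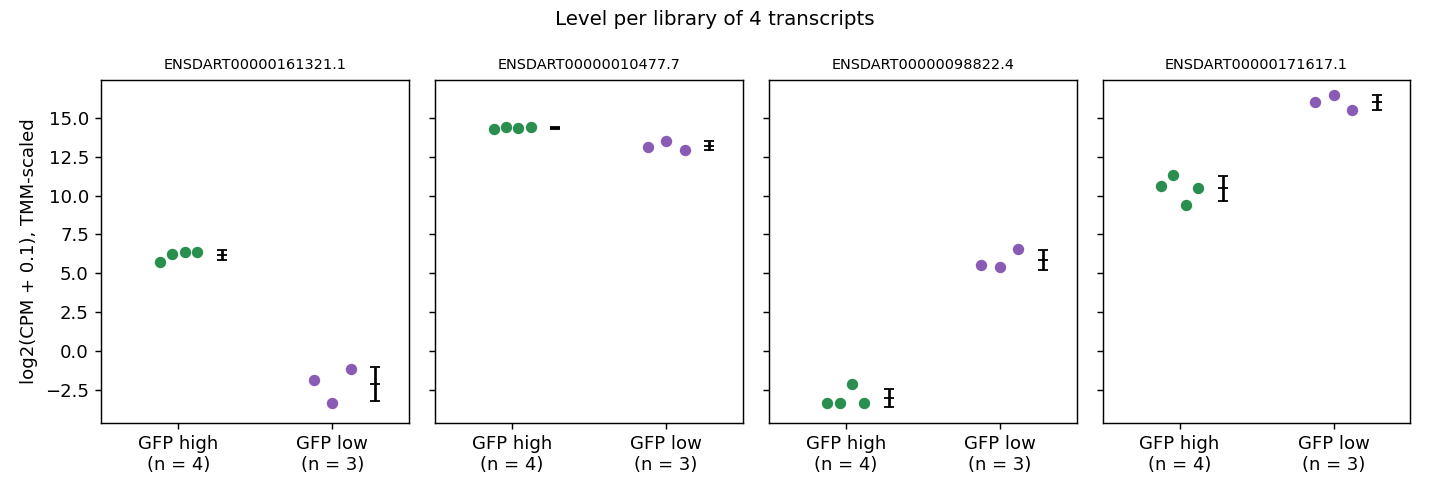
TMM-scaled level of 4 transcripts in each library, as log2(CPM + 0.1) (y axis), for GFP high (green, n = 4) and GFP low (purple, n = 3), with bars for mean ± SD of the log2 values. In each panel all GFP high libraries lie on the same side of all GFP low libraries, and ENSDART00000171617.1 lies highest, in GFP low.

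Some transcripts were found in 1 population only. At least 10 counts in each GFP high library and 0 in all GFP low libraries were seen for 73 transcripts, and the reverse for 82. Set against the limit of 3 counts over the group at 0, the median transcript of the first set was at least 24.4-fold higher in GFP high and that of the second at least 127-fold higher in GFP low. The bound depends on depth, which was lower in GFP low.

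The transcripts higher in GFP low had the higher median length, at 2386 bases, against 1906.5 for those higher in GFP high and 1832 for those not called; transcripts are not independent, and the medians were not tested. The share of calls that were higher in GFP high was 52.5% at no more than 500 bases, 57.7% at 500 to 1000 bases and 32.3% over 5000 bases, falling in each class after the second. The median log2 fold change of all tested transcripts was 0.13, 0.15 and -0.11 in these classes. As a share of tested transcripts, calls higher in GFP high were 8.63% at 500 to 1000 bases and 8.19% over 5000 bases. Calls higher in GFP low were 6.32% and 17.2%, so the falling share followed mainly from more calls in that direction. Length minus effective length, which follows fragment length, was 163 bases ± 2.06 in GFP high (SD, n = 4) and 156 ± 3.93 in GFP low (SD, n = 3), with exact permutation p = 0.0286, the smallest the design allows. This measure was not among the planned tests, and its p is not adjusted.

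None of the 3 measures of library composition passed an adjusted p of 0.05 between the groups in two-sided exact permutation tests. A lone measure at the smallest possible p of 0.0286 is adjusted to 0.0857 over 3 measures. It could not have passed, so this outcome does not show that the groups were alike. The 10 most abundant transcripts took 9.41% ± 0.558 of counts in GFP high (SD, n = 4) and 12.2% ± 2.48 in GFP low (SD, n = 3). The exact p was 0.0286 and the adjusted p 0.0857, with all 3 GFP low libraries above all GFP high libraries. In GFP low replicates 3 to 5 the 10 took 12.1%, 14.8% and 9.84%. ENSDART00000171617.1 alone took 6.92%, 8.73% and 5.26% there. The rest of the 10 took less than the 10 took in any GFP high library, where the lowest was 8.59%. The higher share in GFP low thus came from that transcript. Total counts had exact p = 0.0571 and adjusted p = 0.0857. The number of transcripts detected was 38563 ± 582 in GFP high (SD, n = 4) and 37660 ± 452 in GFP low (SD, n = 3), with exact p = 0.114 and adjusted p = 0.114. At a common depth the numbers detected were 37392 ± 448 and 37251 ± 445, with exact p = 0.686.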

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

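A sample far from the others of its group was looked for in 12 measures of the 4 GFP high libraries; the GFP low group, with 3 libraries, is too small for it. Chance flags about 1 in 20 such groups, and 2 of the 12 were found. The 10 most abundant transcripts took 8.59% of counts in GFP high replicate 2, against 9.58% to 9.75% in the other 3 GFP high libraries. ENSDART00000098822.4 was at 0.124 CPM in GFP high replicate 3 and at 0 in the other 3 GFP high libraries, a difference of 3 counts. In GFP low it was at 42.8 to 94.5 CPM.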

How the results depend on the processing

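Library size alone, the lowess correction on length, the fit on whole counts and the thinned measures of composition were chosen after the data were seen. The count of 7223 transcripts past 5% FDR stayed within 1.5 times under 12 of the 14 alternatives that kept all libraries, from 6436 with at least 5 CPM in 3 libraries to 9230 with DESeq2, as did the counts in each direction and at least 2-fold. The fit on transcripts with whole counts in every library called 2053, 959 higher in GFP high and 1094 in GFP low, 1223 of them at least 2-fold; it tested only 6215 transcripts and kept all 1642 calls that were among them. The replicate block called 2135, 860 higher in GFP high and 1275 in GFP low, 2004 of them at least 2-fold. Only numbers 3 and 4 occur in both groups, and their libraries did not deviate together (r = 0.02 for each number, and -0.036 and -0.0043 when crossed), so the libraries are known to share only a number; 2 numbers cannot exclude pairing, and the block leaves 1 residual degree of freedom. No transcript called both in an alternative and in the main test changed direction, with libraries left out included. Leaving out each library in turn gave 5326 to 6649 calls, 2311 to 3509 higher in GFP high, 2836 to 3495 higher in GFP low and 3894 to 4685 at least 2-fold. Without GFP low replicate 4, 52.8% of calls were higher in GFP high, against 46.7% with all libraries and 42.6% to 48.1% without any other library. The log2 fold changes of the 4 named transcripts kept direction and adjusted p under 0.05 in every alternative that tested them; that of ENSDART00000098822.4 ranged from -13.2 without GFP high replicate 3, which holds its only 3 counts in GFP high and without which the fitted fold is no bound, to -5.12 with limma on log2(TPM + 1). Leaving out each library moved the difference in total counts between 5992595 and 11575725, in transcripts detected between 647 and 1184, and in the share of the 10 most abundant between -4.03 and -1.55 percentage points. With thinned counts the difference in transcripts detected was 140. The test counted by gene and those of gene lists were not run, and mitochondrial transcripts were not removed. Depth limits what is seen below 0.123 to 0.266 CPM.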

Other observations

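The tests on the 139 transcripts below and the lowess correction on length were chosen after the patterns were seen.

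Transcripts at least 8-fold higher in GFP low, with at least 50 CPM there, numbered 139, and their mirror, at least 8-fold higher in GFP high, numbered 65. In the GFP high libraries the first set stood at a median of 4.67%, 6.01%, 3.99% and 5.21% of its GFP low level in replicates 1 to 4. In the GFP low libraries the second set stood at 7.53%, 5.05% and 4.03% of its GFP high level in replicates 3 to 5. The second set was highest in GFP low replicate 3 more often than elsewhere, with 25 and 21 of the 65 transcripts in the 2 orders that begin with it.

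The labels' grouping gave 7223 transcripts past 5% FDR. Only 1 of the 35 splits of the 7 libraries into 4 and 3, the real one, gave as many, and 0.0286 is the smallest share the design allows. This speaks only to how these libraries were assigned to groups. Because the labels do not say whether replicates came from separate animals, it cannot exclude a difference between animals or batches. Other splits mix libraries of both groups, which widens their residual spread, so few calls were likely in them. The highest of the other 34 splits gave 0 by edgeR, and at most 5594 transcripts at an unadjusted p under 0.05, against 11509 in the real split. No other tool was run on the splits.

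The 139 transcripts varied together among the GFP high libraries. Replicate 2 was the highest of the 4 for 51.1% of them and replicate 3 the lowest for 46.8%, and 17.3% showed the commonest complete order, against at most 15.11% for the commonest order in 1000 sets of uncalled transcripts of matched abundance, which argues against a scaling difference. Even carry-over of RNA or cells of the whole GFP low population into the bright gate and graded expression in the bright cells themselves cannot be told apart. For carry-over, the upper limit of 3 of the 139 (2.16%) lay below 0.5 times the least share shown by ENSDART00000171617.1. Chance gives 2.5% for transcripts truly at 0.5 times that share. Even carry-over puts each transcript at or above the full share, where chance gives fewer, so the 2.5% does not explain the 3. Of the 31 transcripts with whole counts, 0 lay below, so the 3 depend in part on how kallisto shared out reads. They are too few to decide. A version without allowance for spread among GFP low libraries and for counting error put 8.63% to 12.2% below. Carry-over would also raise every transcript in replicate 2 over replicate 3 by a like share of its GFP low level, which was 2.85 percentage points for ENSDART00000171617.1 and a median of 2.18 over the set, with a lower quartile of -0.14.

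The GFP low libraries differed more among themselves than the GFP high libraries. Thinned to one depth, over 21797 transcripts with at least 10 counts in every library, the common biological coefficient of variation was 0.276 for the 3 GFP low libraries and 0.186 to 0.202 for the 4 sets of 3 GFP high libraries. At full depth it was 0.28 and 0.198 to 0.212. This coefficient already leaves counting noise out, so thinning could move it little, and the test decides little about depth. The lowest of the 3 GFP low pairs, at 0.249, lay above the highest of the 6 GFP high pairs, at 0.214, which argues against 1 deviating library. No biological explanation was tested, and RNA input and sorting day are not in the labels.

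Fold changes were lower for long than for short transcripts: the median log2 fold change of transcripts of at most 1000 bases exceeded that of transcripts over 3000 bases by 0.24. With offsets for effective length the difference was 0.26. Length minus effective length was 163 bases in GFP high and 156 in GFP low, so these offsets could move the difference only a little. The test therefore cannot weigh other effects of fragment length. A lowess correction on length brought the difference to 0.0011, as it is built to do, and kept 92.8% of the calls. Most calls were bound to remain, since 4724 of the 7223 were at least 2-fold, far above a trend of 0.24. A length trend of that size is unlikely to be the whole cause of the calls, and the correction adds little to this. Whether the trend itself reflects RNA quality, reverse transcription or the kinds of genes expressed was not tested.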
